A study of Mus musculus with 8 samples.

How the data were processed

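Small RNAs from NIH-3T3 cells, an immortalised mouse embryo fibroblast line, were sequenced in 8 libraries from 2 experiments. In the serum experiment, per the labels, cells grown in 10% serum were starved for 48 h, received 20% serum and were collected after 0, 12, 16, 20 and 24 h, which the labels call G0, G1, S, G2/M and G1. In the contact experiment, cells plated at 12% confluency were collected on day 0 (asynchronous) and on days 3 and 5 (both G0). No condition has replicates. For the 1 test between groups, the 3 libraries labelled G0 (serum 0 h, contact days 3 and 5) were set against the other 5.

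The deposited files give, for each library, the distinct 36-nt reads and the count of times each was sequenced, with the 3′ adapter still in the read. Library preparation is described in the labels only by reference to an earlier publication. The read caller, any filter, any alignment and any genome build used by the authors are not given in the sources used here.

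Every file was read in Python 3.11.15 (numpy 2.4.6, scipy 1.17.1, pandas 2.3.3). The adapter TCGTATGCCGTCTTCTGCTTG was removed where at least 6 of its bases were seen, with 1 mismatch allowed per 8 bases. Reads without it were left out. Reads of 2 sequences, AGCGTGTAGGGATCCAAA (18 nt) and GGCATTAACGCGGCCGCTCTACAATAGTGA (30 nt), were taken to be marker oligonucleotides and are called so here. Their origin was not checked against a genome or a protocol, since the sources used held neither. Inserts that shared 12 bases with either, or lay within 3 edits of it by edlib 1.3.9.post1, were removed, as were those with 12 bases of the 5′ adapter, an ambiguous base, or a length outside 16 to 30 nt.

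The reference was GENCODE release M21 (mouse build GRCm38), which holds 1174 miRNA hairpins but no mature sequences, so arms were defined from the reads. Inserts of 18 to 26 nt matching a hairpin perfectly were pooled over all libraries. An arm was kept when it had at least 10 reads, at least 50% of them at 1 5′ end, and a sequence not found in another class of small RNA. This gave 433 mature miRNAs, of which 48 come from more than 1 hairpin and cannot be assigned to 1 of them. A read was counted for a mature miRNA when its first 20 bases were identical, whatever its 3′ end. Names follow the hairpin symbols, so that miR-92-3p, miR-18-5p, miR-301-3p, miR-450-5p, miR-497-5p, miR-146-5p and miR-142-3p stand for products often written with an added a.

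Total reads per library ranged from 707202 to 8512472 and miRNA reads from 137585 to 892528. Intervals are 95% exact binomial (Clopper-Pearson) for shares and 95% exact conditional binomial for ratios. A count of 0 is given the upper limit of 3 counts per library. The reads carry no molecular identifiers, so intervals and limits cover counting error only.

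The test was edgeR 4.0.16 (R 4.3.3) with TMM scaling, robust quasi-likelihood fits, the experiment as a term and 2-sided Benjamini-Hochberg adjusted p under 0.05. It took the 347 miRNAs with at least 10 counts per 1000000 (CPM) in at least 3 libraries. The SE given with a log2 fold change is its absolute value over the square root of the quasi-likelihood F value, and so is derived from the test. It had 5 residual degrees of freedom, and its p-values measure only the spread between these libraries, times and phases included. An interaction term tested whether the G0 difference was unlike in the 2 experiments. Single libraries were compared as ratios of TMM-scaled CPM for miRNAs with at least 100 reads in 1 of the libraries compared. A miRNA was counted when every ratio was at least 2-fold on the same side and every interval excluded 1.

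Lists were tested with camera (limma 3.58.1, preset correlation 0.01), and again with an estimated correlation and with fry. They were the miR-16 family, the miR-322/miR-503 cluster, the miR-17 to miR-92 clusters with their paralogs, the let-7, miR-29, miR-34, miR-30 and miR-181 families, growth-factor or serum responsive miRNAs, the miR-23, miR-27 and miR-24 clusters, the miR-99, miR-100, miR-125 and miR-10 list, fibroblast or mesenchymal miRNAs, the Dlk1-Dio3 locus, the miR-130, miR-301, miR-148 and miR-152 list, and miRNAs of other cell types (epithelial, muscle, blood, neural, pluripotent or germ line, liver). The miR-26 family and the miR-221 and miR-222 pair, with fewer than 3 members, are given by member. Of the lists of other cell types, only the pluripotent or germ line list had enough members past the filter to be tested alone. These lists were also tested pooled, with 7 of 25 members past the filter. The summed share of the miR-16 family was compared by an exact permutation test over all 56 splits of the libraries, and the 3p to 5p ratio of miR-322 was taken per library, since it was the only pair of the family and the cluster with 10 or more reads of each arm in every library.

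Named miRNAs were up to 10 called in each direction, up to 8 in each direction with the widest smallest ratio in each comparison of single libraries, every tested member of the miR-16 family and the miR-322/miR-503 cluster, the most abundant and the farthest moved member of every other list, and the 5 most abundant miRNAs. Abundance was the mean TMM-scaled CPM over the libraries. The groups, comparisons, tests, thresholds, lists, naming rule and the first set of alternatives were set before the data were examined. The adapter and marker steps and the definition of arms were set from the reads.

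This first set held DESeq2 size factors or total reads as scaling, no filter, the Wald test of DESeq2 1.42.0, no experiment term, 18 bases for counting, 5′ ends shifted by up to 2 nt, whole reads matching the hairpin, a 1.5-fold threshold, a minimum of 500 reads, other denominators, and each library left out. Added after the data were seen were an offset for GC content (a loess of span 0.75 per library), labels exchanged within experiments, a family sum in CPM, the miRNAs shared by the serum and contact comparisons under other scalings, and single libraries left out of 2 more comparisons. The median shift of a library's miRNAs under total reads rather than TMM scaling lay between −0.84 and 0.52 on the log2 scale.

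The counting step was tested on 43300 simulated reads with a 0.5% error per base. Of these 90.2% were counted for the right miRNA, 12 reads for a wrong one, and 0 of 20000 random reads for any. The random reads were strings of random bases, for which 20 identical bases are all but impossible. They do not measure false counts from other RNAs. The edgeR test was run on 10 simulated sets of 347 miRNAs with 60 changed in each. It called 1.5% of 2-fold, 20% of 4-fold and 34% of 8-fold changes, and 5.93% of its calls were false. Figures were drawn with matplotlib 3.10.9.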

Results

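The data were 8 small-RNA libraries of NIH-3T3 fibroblasts, which ask how miRNA levels differ between cells arrested by serum starvation or contact inhibition and other cells. Per library, 6121247 reads (serum 0 h), 8512472 (12 h), 7071603 (16 h), 7087714 (20 h), 7449478 (24 h), 707202 (contact day 0), 763334 (day 3) and 801593 (day 5) were deposited. Of these, 237905, 203125, 892528, 183705, 137585, 326089, 438098 and 462212 in the same order were counted for a miRNA. In the serum libraries most other reads were taken to be marker oligonucleotides, which made up 62.5%, 94.7%, 78.5%, 94.2% and 95.3% of reads at 0, 12, 16, 20 and 24 h, against 0.0395%, 0.0351% and 0.00437% on contact days 0, 3 and 5. In the 0 h library a further 27.9% of reads held inserts shorter than 16 nt.

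By mean TMM-scaled CPM over all libraries, the 5 most abundant miRNAs were miR-199a-3p, miR-21a-5p, miR-125b-5p, let-7f-5p and let-7d-5p. This ranking rests on the scaling. TMM factors of 0.558 to 0.808 in the contact libraries and 1.17 to 1.43 in the serum libraries give the contact libraries more weight than shares of miRNA reads do. miR-199a-3p, identical to miR-199b-3p and made from mesenchymal miRNA genes, had a mean of 95292 counts per 1000000 (CPM) and took between 1.98% of miRNA reads (contact day 0) and 16.1% (day 5). miR-21a-5p, a growth-factor responsive miRNA inside the Vmp1 gene, had a mean of 80526 CPM. miR-125b-5p had a mean of 77184 CPM and made up 16.5% of miRNA reads at serum 12 h but 1.82% on contact day 5. let-7f-5p had a mean of 65029 CPM. let-7d-5p had a mean of 59744 CPM and ranged from 0.814% of miRNA reads at serum 20 h to 14.0% on contact day 0.

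The first comparison asked which miRNAs differed between the 3 G0 libraries and the other 5. miR-503-5p was 3.23 log2 units (SE 0.59) higher in the G0 libraries, with 3027 CPM at serum 0 h, 3117 on contact day 3 and 6975 on day 5. It stood between 217 CPM (serum 12 h) and 744 CPM (16 h) in the other 5 libraries, so each of the 3 G0 libraries lay above each of the others. miR-503 is a relative of miR-16 whose hairpin lies next to that of miR-322 on the X chromosome. miR-10a-5p, encoded within the Hoxb gene cluster, was 3.04 log2 units (SE 0.66) higher in G0. miR-29b-5p, made from 1 of the 2 hairpins that give miR-29b-3p, was 3.65 log2 units (SE 0.83) lower. The high miR-10a-5p level was in 1 G0 library, with 2708 CPM at serum 0 h against 94.2 to 177 CPM in the released cells, and 48.9, 45.2 and 140 CPM on contact days 0, 3 and 5.

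These 3 miRNAs were called by edgeR among 347 tested, with adjusted p of 0.00923 for miR-503-5p, 0.0328 for miR-10a-5p and 0.0349 for miR-29b-5p, and 39 miRNAs had an unadjusted p under the same threshold. miR-503-5p was higher in 3 of 3 G0 libraries, and miR-29b-5p was lower at serum 0 h (8.79 CPM) than in the 4 released libraries (74.5 to 281 CPM) and lower on contact days 3 and 5 (496.9 and 93.1 CPM) than on day 0 (2477 CPM). The mature sequences were TAGCAGCGGGAACAGTACTGCAG for miR-503-5p (GRCm38, chromosome X, 53054027 to 53054049, minus strand, no other gene), TACCCTGTAGATCCGAATTTGT for miR-10a-5p (chromosome 11, 96317186 to 96317207, plus strand, no other gene) and GCTGGTTTCATATGGTGGTTTAGA for miR-29b-5p (chromosome 6, 31063065 to 31063088, minus strand, no other gene). Without serum 0 h edgeR called 0 miRNAs (21 unadjusted), with miR-503-5p at 4.01 (adjusted p 0.216), miR-10a-5p at 1.13 (0.9996) and miR-29b-5p at −2.70 (0.558), and without serum 24 h it called 0 (20 unadjusted), with adjusted p of 0.0739, 0.0739 and 0.241 in the same order. miR-503-5p was the only call without serum 20 h, where adjusted p was 0.0705 for the other 2, and without contact day 5 (0.0524 and 0.0685). Without contact day 0 there were 2 calls, with miR-503-5p at 2.80 (0.0517) and miR-29b-5p at −4.40 (0.564), and there were 5 without contact day 3 and 12 without serum 16 h, miR-503-5p among both. DESeq2 called 14, edgeR without a filter 8 and without the experiment term 1 (miR-503-5p), and miR-29b-5p lost its call with total-read scaling (adjusted p 0.0974), which called miR-376a-3p instead (log2 fold change 3.08). It also lost its call with 18 bases for counting (0.0848) and with whole reads matching the hairpin (0.0861), which left 2 calls each.

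**Figure D1:**
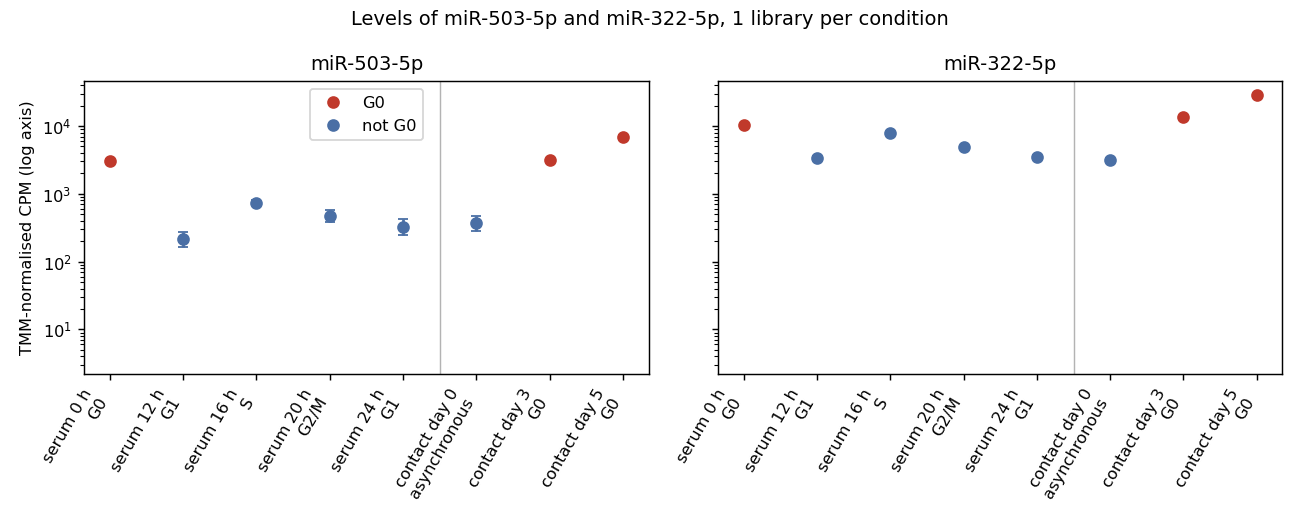
TMM-normalised CPM (log axis) of miR-503-5p and miR-322-5p in each of the 8 libraries, with G0 libraries in red, others in blue, and bars for the 95% counting interval. The 3 G0 libraries of miR-503-5p sit between 3027 and 6975 CPM and the other 5 between 217 and 744 CPM.

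**Figure D2:**
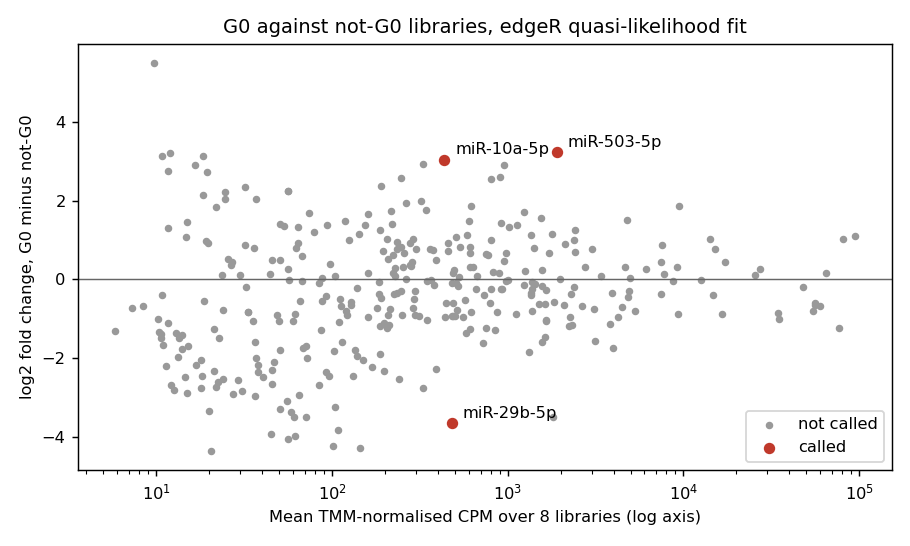
Log2 fold change of each of the 347 tested miRNAs, G0 minus the other libraries, against mean CPM over the 8 libraries (log axis), with the 3 called miRNAs in red. miR-503-5p (3.23) and miR-10a-5p (3.04) lie above 0 and miR-29b-5p (−3.65) below.

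The miR-322/miR-503 cluster is a run of miRNA genes on the X chromosome. Its miR-503 and miR-322 (the mouse counterpart of human miR-424) are linked to withdrawal from the cell cycle. As a list the cluster was higher in G0 by camera with the preset correlation (adjusted p 0.00142). It was not called with an estimated correlation (adjusted p = 0.645) or by fry (0.219). Of its 8 members 7 had positive values, 1 passed the test over all miRNAs and 2 passed when adjusted over the list alone (miR-503-5p and miR-322-5p). miR-322-5p (CAGCAGCAATTCATGTTTTGGA, chromosome X, 53054306 to 53054327) was 1.86 log2 units higher (SE 0.55, adjusted p 0.156), with 10518, 13462 and 28699 CPM in the G0 libraries and 3156 to 7814 CPM in the other 5. Values for the rest, none past the test, were 0.95 for miR-322-3p, 2.36 for miR-542-3p, 0.25 for miR-542-5p, 1.47 for miR-450-5p and 2.74 for miR-450b-5p, and −0.28 for miR-351-5p.

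The miR-34 family, miRNAs induced by p53, was also higher in G0 as a list by camera with the preset correlation (adjusted p 0.0143). It was not called with an estimated correlation (adjusted p = 0.760) or by fry (0.219). Of its members 3 of 3 were positive, 0 past the test over all miRNAs by edgeR and 2 when adjusted over the list alone. miR-34b-5p stood at 2.60 (SE 0.76, adjusted p 0.156) and miR-34c-5p at 1.25 (SE 0.50, 0.349). Without contact day 0 camera called 0 lists, and without contact day 3 it called 1, with the miR-34 family at an adjusted p of 0.0530.

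The miR-16 family, whose members repress D-type and E-type cyclins, did not pass as a list (camera adjusted p 0.429), with 3 of its 6 members positive and 1, miR-322-5p, called when adjusted over the list alone. Values were 1.13 for miR-15a-5p, −0.76 for miR-15b-5p, −0.01 for miR-16-5p, −0.02 for miR-195a-5p and 0.82 for miR-497-5p, and with total reads as scaling those of miR-16-5p and miR-195a-5p were positive (0.23 and 0.21). The growth-factor or serum responsive list (camera adjusted p 0.718, 2 of 6 positive, 1 when adjusted over the list alone) held miR-155-5p, an inducible miRNA of activated cells, at −3.49 (SE 0.90, adjusted p 0.0868) and miR-21a-5p at 1.03. In the let-7 family, repressors of Ras and Hmga2, 4 of 9 members were positive and 0 were called by edgeR over all miRNAs or adjusted over the list alone (camera adjusted p 0.429), with let-7e-5p at −0.99 and let-7f-5p at 0.16.

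The remaining lists were not called by camera. The miR-29 family (adjusted p 0.429, 2 of 3 positive) had miR-29a-3p at −0.60 and miR-29c-3p at 1.57, the second past the test adjusted over the list alone. The miR-17 to miR-92 clusters and their paralogs, promoters of proliferation, had 5 of 9 positive (adjusted p 0.718), with miR-17-5p at −1.13 and miR-19a-3p at 2.00. The miR-23, miR-27 and miR-24 clusters (adjusted p 0.776, 1 of 5 positive) held miR-23b-3p at −0.65 and miR-24-3p at −0.18, the latter 0.08 with total-read scaling. The miR-30 family (0.776, 3 of 5 positive) held miR-30e-5p at 1.77 and miR-30d-5p at −0.69. The miR-181 family (0.662, 3 of 4 positive) held miR-181c-5p at 1.40 and miR-181a-5p at −0.13, the latter 0.07 with total-read scaling. Of the fibroblast or mesenchymal list 5 of 7 were positive (0.680), among them miR-199a-3p at 1.09, and of the miR-130, miR-301, miR-148 and miR-152 list 3 of 5 (0.429), among them miR-130a-3p at 0.78 and miR-301-3p at 1.70.

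In the miR-99, miR-100, miR-125 and miR-10 list the median (−0.24), the mean (0.18) and the test (down, adjusted p 0.977) differed in sign, with miR-10a-5p on the positive side and miR-125b-5p at −1.23 (adjusted p 0.180), both past the test adjusted over the list alone. In the Dlk1-Dio3 locus, an imprinted run of miRNA genes, 13 of 32 members were positive, and the median (−0.25) and fry (down, adjusted p 0.962) stood against the mean (0.06) and camera (up, adjusted p 0.776), with miR-376a-3p at 2.90 (adjusted p 0.0911, called adjusted over the list alone) and miR-127-3p at −0.03. By fry's mixed test, which asks for change in either direction, the miR-322/miR-503 cluster, the growth-factor or serum responsive list and the miR-99, miR-100, miR-125 and miR-10 list had an adjusted p of 0.0412. In the pairs given by member, miR-222-3p, a repressor of p27, stood at −0.87, miR-26a-5p at 0.12 and miR-26b-5p at 0.31.

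Whether the G0 difference was unlike in the 2 experiments was tested with an interaction term. No miRNA was called, with miR-503-5p among those tested. The count was 0 by edgeR (14 unadjusted, smallest adjusted p 0.864), 0 with DESeq2 size factors in edgeR (13 unadjusted), 0 without a filter (20 unadjusted) and 0 by the DESeq2 Wald test (22 unadjusted, smallest adjusted p 0.183). Serum G0 and contact day 0 had 1 library each, and the edgeR test found 34% of simulated 8-fold changes in the simpler comparison.

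The second comparison set starved cells against the released ones. The labels name no library from before starvation, so starved and released cells differ in arrest and in added serum at once. miR-155-5p (chromosome 16, 84714143 to 84714166, exon of Mir155hg) stood at 41.0 CPM at 0 h and at 2520, 1544, 1236 and 1535 CPM at 12, 16, 20 and 24 h, with ratios of 0.0163 to 0.0332. miR-503-5p stood higher at 0 h, by 4.07-fold over 16 h to 14.0-fold over 12 h, as did miR-10a-5p by 15.3-fold to 28.8-fold. Higher by smaller ratios to the closest library were miR-33-5p, a regulator of cholesterol export inside Srebf2 (2.50-fold), miR-329-5p of the Dlk1-Dio3 locus (3.05-fold) and miR-669c-5p (2.31-fold). miR-200c-3p (1037 CPM), miR-141-3p (454 CPM) and miR-200b-3p (419 CPM), miRNAs of epithelial cells, were at least 62.4-fold, 27.3-fold and 25.2-fold higher at 0 h than in the closest library with a count of 0, set at 3 counts per library, and miR-200c-3p had 9 reads at 16 h.

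Of 225 miRNAs with enough reads, 9 were at least 2-fold higher at 0 h than in each released library and 14 lower, against 12 and 11 with total reads as scaling. Lower with the closest ratio in each case were miR-29b-5p (3 reads, 0.118, 95% interval 0.0225 to 0.395), miR-674-3p (0.182), miR-324-3p (0.191), miR-323-3p (0.285), miR-146b-5p, a miRNA of inflammatory signalling (0.318), miR-365-2-5p (0.323) and miR-872-3p (0.328). Set against the other serum libraries in the same way, serum 12 h gave 43 miRNAs, 16 h 5, 20 h 4 and 24 h 9, so that the 23 at 0 h did not exceed the number that a released library gave. Without serum 16 h, which takes away a ratio that must pass, the count was 48, and with a minimum of 500 reads it was 8.

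The third comparison followed cells into contact inhibition. miR-503-5p was 8.44-fold higher on day 3 than on day 0 (95% interval 6.60 to 10.9) and 18.9-fold on day 5 (14.8 to 24.4), and miR-322-5p 4.27-fold and 9.09-fold. miR-34b-5p, induced by p53, was 14.3-fold and 16.4-fold higher, and miR-376a-3p and miR-136-5p of the Dlk1-Dio3 locus were 12.0-fold and 11.1-fold higher on day 3 and 26.4-fold and 32.3-fold on day 5. miR-29b-3p, a repressor of collagens, was 7.88-fold and 6.49-fold higher, miR-19a-3p 6.79-fold and 6.86-fold, miR-301-3p 5.60-fold and 11.4-fold, and miR-101b-3p 5.54-fold and 8.65-fold. let-7b-5p was lower, at 0.404 and 0.281 of its day 0 level, as was miR-145a-5p, a miRNA of smooth muscle and fibroblasts, at 0.339 and 0.361.

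Of 167 miRNAs, 29 were at least 2-fold higher on both later days and 21 lower, against 40 and 6 with total reads as scaling, which left let-7b-5p at a log2 ratio of −0.79 and miR-151-3p at −0.99 on the closer day. Other lower miRNAs were miR-29b-5p (0.201 on day 3 and 0.0376 on day 5), the muscle miRNA miR-206-3p (0.216 and 0.147), miR-669c-5p (0.255 and 0.201), miR-574-5p (0.270 and 0.186), miR-744-5p (0.345 and 0.332) and miR-151-3p (0.351 and 0.398). Day 5 set against days 0 and 3 gave 58 miRNAs, more than the 50 for day 0, and day 3 gave 7. Without day 3, which takes away a ratio that must pass, the count was 103, and with a minimum of 500 reads it was 24.

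Between the serum and contact comparisons, 165 miRNAs had enough reads in both. miR-503-5p and miR-33-5p were higher in arrest in both, where independent lists would share 0.879, and miR-155-5p and miR-29b-5p were lower in both, where 1.02 would be shared. With total reads as scaling miR-376a-3p and miR-210-3p were also higher in both, and miR-155-5p was no longer lower in both, at 0.587 of its day 0 level on day 3. With DESeq2 size factors miR-376a-3p was also higher in both. miR-669c-5p was higher in starved cells and lower in contact-inhibited ones, and 0 miRNAs went the other way.

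The fourth comparison asked how far miRNAs varied among the released libraries labelled G1, S, G2/M and G1. miR-7-5p, made in part from an intron of Hnrnpk, was not seen at 12 h and stood at 1251, 916 and 1834 CPM at 16, 20 and 24 h, at least 172-fold apart. miR-9-5p and miR-128-3p, miRNAs of neural cells, were at least 52.8-fold and 50.5-fold apart and miR-29a-5p at least 47.0-fold, each also at a count of 0 at 12 h. miR-33-5p (1 read at 12 h, 123-fold apart, 95% interval 22.02 to 4882), miR-421-3p (2 reads, 48.7-fold, 13.1 to 409.2) and miR-186-5p (7 reads, 46.4-fold, 22.2 to 116) were lowest at 12 h too. miR-291a-3p, a miRNA of pluripotent cells, went the other way, with 408 CPM at 12 h and a count of 0 in the other 3, at least 141.7-fold apart.

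Of the miRNAs with enough reads, 69.4% were at least 2-fold apart between the highest and lowest released library, and the lowest was serum 12 h for 66 of them. Serum 12 h and 24 h, both labelled G1, differed by at least 2-fold in 44 of 149 miRNAs. Serum 12 h held 233 of the miRNAs at a common depth of 137585 reads, and the other 7 libraries between 304 and 369.2. The share was 46.5% (101 miRNAs) without serum 12 h, 40.1% (63) without 16 h and 55.2% (69) with a minimum of 500 reads, while miR-7-5p, miR-9-5p and miR-128-3p had their extreme at 12 h.

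The summed miR-16 family, miRNAs that share the seed AGCAGCA, took 3.71% of miRNA reads at serum 0 h (95% interval 3.63 to 3.79%) and 2.22% at 12 h (2.15 to 2.28%), 3.15% at 16 h, 2.91% at 20 h and 2.65% at 24 h. It took 1.35% on contact day 0 (1.31 to 1.39%), 2.91% on day 3 (2.87 to 2.97%) and 2.52% on day 5 (2.48 to 2.57%). miR-322-5p alone made up 1.51% of miRNA reads at serum 0 h and 0.460% to 0.912% in the released libraries, and 0.178%, 1.09% and 1.60% on contact days 0, 3 and 5. miR-16-5p took 1.59% at 0 h, 1.47% to 1.70% after release and 0.659%, 1.31% and 0.619% in the contact libraries.

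The family's mean share was 3.05% ± 0.605 (SD, n = 3) in G0 and 2.46% ± 0.708 (SD, n = 5) elsewhere, 0.592 points apart (exact permutation test, 2-sided, p = 0.321). Within experiments the G0 libraries were 0.976 points higher in the serum cells and 1.37 points higher in the contact cells (exact p = 0.0667, the smallest that exchange within experiments allows). As TMM-scaled CPM the family stood at 35712 ± 9685 (SD, n = 3) and 21946 ± 4144 (SD, n = 5), 13765 apart (exact permutation p = 0.0357), and within experiments 10544 apart (exact p = 0.200), with miR-16-5p itself near 0 in the fold change of the test. The first of these tests ignores the experiment. Serum 0 h (25860 CPM) lay below 16 h (27007) and above the other released libraries. Contact days 3 and 5, at 36054 and 45221 against 23968 on day 0, carried the higher G0 mean. Without serum 0 h the difference in share was 0.262 points and without contact day 0 it was 0.316 points.

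**Figure D3:**
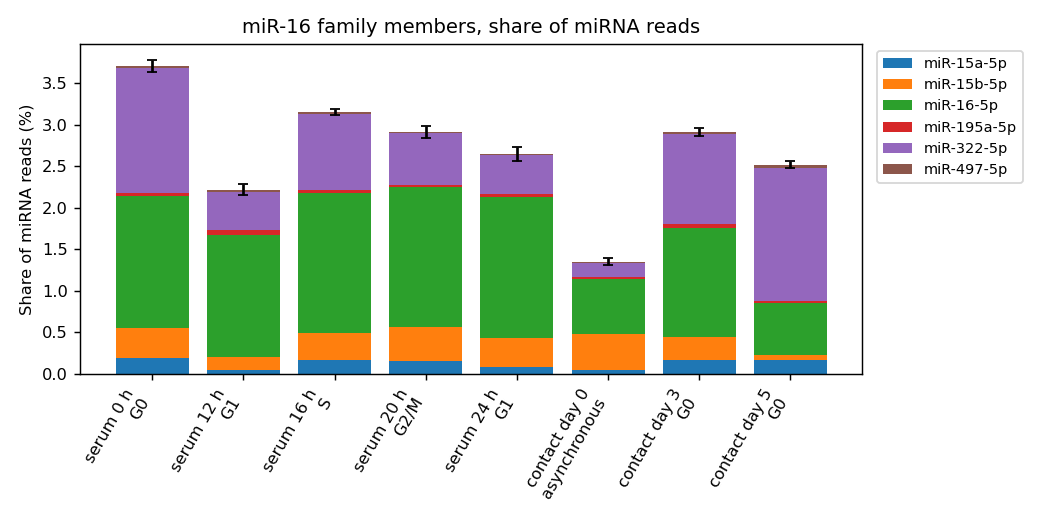
Share of miRNA reads (percent, from 0) taken by each member of the miR-16 family in the 8 libraries, stacked, with the 95% counting interval of the sum. The sum runs from 1.35% on contact day 0 to 3.71% at serum 0 h, and the miR-322-5p part from 0.178% to 1.60%.

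miR-322-3p, the arm opposite miR-322-5p, was counted at 3.54, 7.82, 1.66, 3.74 and 7.11 reads per 100 reads of miR-322-5p at serum 0, 12, 16, 20 and 24 h, and at 4.13, 2.27 and 0.852 on contact days 0, 3 and 5. The mean was 2.22 ± 1.34 (SD, n = 3) in G0 and 4.89 ± 2.54 (SD, n = 5) elsewhere. This difference of −2.67 is close to the SD of the second group, and was not tested. With 5′ ends shifted by up to 2 nt the means were 3.99 ± 3.06 and 7.11 ± 3.21, a difference of −3.11, and the values at serum 0 h and 16 h were 7.37 and 3.82.

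miRNAs of cell types other than fibroblasts were summed per library. The epithelial list reached 3047 reads per 1000000 miRNA reads (ppm) at serum 0 h, from 5 of its 7 members, in the same library that held the high miR-10a-5p level and 1 of the 3 high miR-503-5p levels. Elsewhere it stood at 0 (12 h, up to 14.8), 14.6 (16 h), 65.3 (20 h), 0 (24 h, up to 21.8), 6.13 (day 0), 11.4 (day 3) and 6.49 (day 5). The blood list reached 450 ppm at serum 0 h and 9.13 on day 3, and had 0 reads at 12, 20 and 24 h, which allows up to 14.8, 16.3 and 21.8. It stood at 2.24 at 16 h, 6.13 on day 0 and 4.33 on day 5. The pluripotent or germ line list reached 985 at serum 12 h and 219 at 0 h, and at most 79.7 elsewhere (day 0). The muscle list, with miR-206-3p as its main member, ran from 84.4 (day 5) to 592 (day 0), and the neural list from 0 (12 h, up to 14.8) to 979 (16 h). The liver list, miR-122-5p, could not be assessed. It was not among the mature miRNAs kept, so none of its reads could be counted and no upper limit can be given. Members of the other lists that were not kept add no reads to the sums in the same way. The limits given above for lists without reads therefore cover their kept members only.

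As a group the members of these lists that passed the filter were not called between G0 and the other libraries (camera adjusted p 0.977, 2 of 7 positive), nor was the pluripotent or germ line list (adjusted p 0.776, 1 of 3 positive), whose median and mean were negative (−1.70 and −0.53) while camera gave up. The 7 were muscle, neural and pluripotent or germ line miRNAs. No epithelial or blood miRNA passed the filter, so this test could not assess the epithelial and blood lists, both highest at serum 0 h. Values were −0.92 for miR-206-3p, −2.61 for miR-1a-3p, 0.37 for miR-9-5p, −1.70 for miR-291a-3p and 2.21 for miR-295-3p.

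**Figure D4:**
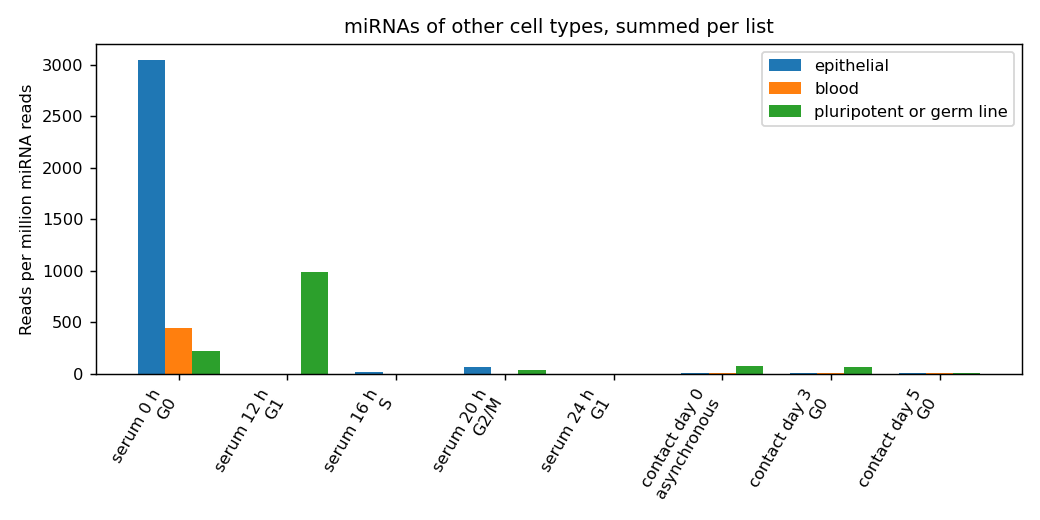
Reads per 1000000 miRNA reads summed over the epithelial, blood and pluripotent or germ line lists in the 8 libraries, with bars starting at 0. The epithelial list stands at 3047 at serum 0 h and at 65.3 or less elsewhere, and the pluripotent list at 985 at serum 12 h.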

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

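Of the tests in this part, the count of splits for the lists, the total-read and DESeq2 scalings and the interaction term were planned. The scalings were applied to miR-503-5p as a test of an explanation, and the other tests of explanations were chosen, only after the result they measure was seen.

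The 3 calls between G0 and the other libraries, miR-503-5p, miR-10a-5p and miR-29b-5p, were set against other splits of the 8 libraries into 3 and 5. As many calls came from 2 of the 55 splits that could be fitted, the real one included, a share under 0.05, but these splits exchange libraries between the experiments, and another gave 11. Of the 15 splits that took 1 serum and 2 contact libraries, as the real one did, 1 gave as many, the real one itself, and the highest other gave 0. A set of 15 is too few for a share under 0.05. The split with 11 calls joined serum 0 h, serum 16 h and contact day 5. Serum 0 h and contact day 5 are also in the real G0 group, so these calls do not by themselves show a structure other than the cell-cycle labels. These 3 libraries have the most negative slopes of miRNA level on GC content (−0.0196, −0.0296 and −0.0375 log2 units per percent). With a GC offset this split gave 3 calls, while the real split gave 8 and the highest other 5. A GC trend may therefore account for most of the 11 calls. The fold changes of the real split also fell with GC content (Spearman rho −0.290 across miRNAs, −0.0606 with the offset). Slopes were 0.0118 and −0.0156 on contact days 0 and 3, and 0.0496 at serum 12 h, the steepest of all libraries. Ratios between single libraries may therefore carry a GC trend too, and were not corrected for it. For the 2 lists called by camera, the miR-322/miR-503 cluster and the miR-34 family, 8 of the 55 splits gave as many (highest other 3), and chance is not excluded. Of the 15 splits within the experiments 5 did (highest other 3).

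The higher miR-503-5p of the G0 libraries was weighed against a GC trend, the scaling and RNA from other cells. With the GC offset its log2 fold change was 3.68 and called, above the 3.23 without it, so removing the GC trend did not lower the value. The lower of the values with total-read and DESeq2 scaling was 3.18, both called, which argues against the scaling as the whole cause. In the contact cells, where the epithelial list stayed at or under 11.4 reads per 1000000 miRNA reads (ppm), the smaller ratio of a later day to day 0 was 8.44 (95% interval 6.60 to 10.9), which RNA of epithelial cells cannot account for. At serum 0 h that list stood at 3047 ppm, so RNA from other cells, or from another library, and starvation cannot be told apart for the serum part, 1 library holding both. An effect of arrest itself stays open as a hypothesis. The lowest G0 library stood 4.07-fold (3.70 to 4.47) over the highest other, but that order is part of the pattern for which miR-503-5p was picked, so it adds no support.

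miR-10a-5p was called higher in G0 on the level of serum 0 h alone. A difference of like size was not seen in the contact libraries. Day 3 stood at 0.924 of day 0 (95% interval 0.384 to 2.37) and day 5 at 2.86 (1.35 to 6.74). The smallest ratio of 0 h to a released library was 15.3 (11.5 to 20.7). These intervals cover counting error only, and the interaction term did not call miR-10a-5p. Whether an effect of arrest is shared by both experiments thus stays open. RNA from other cells may have brought the high miR-10a-5p level: the epithelial list of 7 miRNAs, none of them picked from these libraries and with miR-200c-3p (1037 CPM) and miR-141-3p (454 CPM) as its most abundant members, was 46.6 times as high at 0 h as in the next library. RNA or reads carried over from a library outside this series would give the same values, and nothing in these data separates it from other cells in the culture. An effect of serum starvation itself stays open, since only 1 library holds starved cells and it is the same one. No sort or gate that would remove other cells is described.

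Reads taken to be marker oligonucleotides were 62.5%, 94.7%, 78.5%, 94.2% and 95.3% of reads at serum 0, 12, 16, 20 and 24 h, far above the contact libraries. The epithelial list at serum 0 h (3047 ppm), the blood list in the same library (450 ppm, 107 reads) and the pluripotent or germ line list at serum 12 h (985 ppm, 200 reads) were above the limit that a count of 0 allows. Whether they came from cells in the culture or from another library is not known. miR-669c-5p was higher at serum 0 h than in every released library (2.31-fold over the closest) and lower on both later contact days (0.255 of day 0 on the closer). The interaction term tested this difference and did not call it (log2 −4.31, unadjusted p 0.0502, adjusted p 0.864).

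Among the 5 libraries not in G0, 1 stood apart from the rest for 13 of 46 named values. Such a rule marks about 1 group in 20, or about 2.3 of these, when all values of a group come independently from 1 normal population. Here 1 library comes from the other experiment and the named values are not independent. The excess over 2.3 therefore cannot be read as a result against chance. Contact day 0, the only contact library of the 5, held the highest CPM of miR-29b-5p (2477, others at most 281), let-7f-5p (99777, at most 26825), let-7e-5p (133611, at most 8246), miR-222-3p (19709, at most 9817), miR-24-3p (88945, at most 33506), miR-181a-5p (2298, at most 1115) and miR-206-3p (1032, at most 299.2), and the lowest of miR-127-3p (5003, others at least 10550). Serum 16 h, the deepest in miRNA reads, held the highest CPM of miR-450b-5p (28.8, others 0), miR-19a-3p (317, at most 139), miR-34b-5p (616, at most 227) and miR-21a-5p (79379, at most 47387). Serum 12 h held the highest of miR-291a-3p (408, at most 81.5).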

How the results depend on the processing

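The GC offset, exchange within experiments, the family sum in CPM, the overlap of comparisons under other scalings and the libraries left out of the contact and released comparisons were chosen only after the results were seen. For 45 named miRNAs, 364 of 404 fold changes under other settings and 305 of 357 with 1 library left out kept their sign and their side of the threshold, 5 and 12 lost a call, 10 and 8 gained one, and 25 and 32 changed sign, none of them called. miR-503-5p kept its sign in 17 of 17 alternatives and its call in 14 (2.80 to 4.01), miR-10a-5p in 17 and 12 (1.13 to 4.32) and miR-29b-5p in 17 and 8 (−4.57 to −1.70). Calls numbered 8 without a filter, 14 by DESeq2, 1 without the experiment term, 8 with the GC offset, and 0 to 12 with 1 library left out (0 without serum 0 h or 24 h, 1 without serum 20 h or contact day 5, 5 without contact day 3, 12 without serum 16 h). Those without a filter held miR-141-3p, miR-200b-3p and miR-200c-3p, seen almost only at serum 0 h. The 0 h comparison gave 35 miRNAs at 1.5-fold, 8 with 500 reads, and 24 to 48 with a library left out (48 without serum 16 h). The contact comparison gave 78, 24, and 60 to 103 (103 without day 3), and the released one 69 with 500 reads and 63 to 140 (63 without serum 16 h, 101 without 12 h). Lists numbered 0 with an estimated correlation, 0 by fry in 1 direction (3 by its mixed test) and 0 to 2 with a library left out (0 without contact day 0, 1 without contact day 3). The miR-16 family difference of 13765 CPM had an exact p of 0.0357, against 0.200 for 10544 CPM within experiments and 0.321 for the share. A higher read minimum changes how many miRNAs can count, and a lower fold lets smaller ratios count. Fewer libraries change the spread in the test. In the 0 h and contact comparisons a library left out takes away a ratio that must pass. In the released comparison it can only narrow the span from highest to lowest. The rule itself thus moves these counts. For all other changes in this part the cause was not tested. Log2 values that changed sign were, with total reads, 0.23 for miR-16-5p, 0.21 for miR-195a-5p, 0.078 for miR-24-3p, 0.070 for miR-181a-5p and 0.085 for miR-127-3p. Without the experiment term they were 0.029 for miR-16-5p, 0.41 for miR-195a-5p, 0.29 for miR-17-5p, 0.31 for let-7e-5p, 0.64 for miR-24-3p, −0.13 for miR-26b-5p and 0.16 for miR-181a-5p. With 18 bases they were 0.11 for miR-16-5p, 0.10 for miR-195a-5p and 0.053 for miR-127-3p, and with whole reads 0.18 for miR-195a-5p, 0.000453 for miR-351-5p and 0.44 for miR-127-3p. With the GC offset they were 0.017 for miR-16-5p, 0.36 for miR-351-5p, −0.45 for let-7f-5p, 0.21 for miR-24-3p, −0.16 for miR-26a-5p, −0.25 for miR-26b-5p and 0.46 for miR-127-3p. With 1 library left out, values ran from −1.45 to 0.052 for miR-15b-5p, −0.19 to 0.54 for miR-16-5p, −0.42 to 0.77 for miR-195a-5p, −0.91 to 0.69 for miR-351-5p, −0.022 to 0.78 for miR-542-5p, −0.28 to 0.94 for let-7f-5p, −0.44 to 0.20 for miR-24-3p, −0.078 to 0.57 for miR-26a-5p, −0.070 to 1.06 for miR-26b-5p, −0.41 to 0.33 for miR-181a-5p, −0.12 to 2.34 for miR-199a-3p, −0.60 to 0.29 for miR-127-3p, −2.15 to 0.26 for miR-206-3p, −6.75 to 0.058 for miR-1a-3p, −0.25 to 1.40 for miR-9-5p, −2.26 to 1.80 for miR-291a-3p and −1.45 to 4.64 for miR-295-3p. miR-450b-5p, seen in 1 of the libraries not in G0, passed the filter in 14 of the alternatives, and under 18 bases some miRNAs share a name and gave no value. Depth limits the 137585 miRNA reads of serum 24 h most, where a count of 0 allows 21.8 reads per 1000000.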

Other observations

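The test of the hypothesis in this part was chosen only after the result was seen.

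The let-7 family, which represses growth-promoting genes such as Ras and Hmga2, took 56.6% of miRNA reads on contact day 0 (95% interval 56.4 to 56.8%), 41.9% on day 3 and 33.5% on day 5. In the serum cells it took 13.2%, 13.4%, 16.1%, 10.3% and 16.6% at 0, 12, 16, 20 and 24 h. The labels describe no difference between the experiments other than the treatment. The libraries of the 2 experiments also differed in total reads, in marker reads and in reads without an adapter. The last were 1.26 to 2.25% of reads in the serum libraries and 23.3 to 32.3% in the contact libraries. A difference in preparation or sequencing therefore cannot be told apart from one between the cells.

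miR-29b-5p comes from 1 hairpin (chromosome 6), while miR-29b-3p pools that hairpin and a second on chromosome 1, so their ratio also moves with the output of the second hairpin. Per 100 reads of miR-29b-3p, miR-29b-5p had 0.134 at serum 0 h (3 against 2232 reads, 95% interval 0.0277 to 0.393), 2.68, 3.10, 3.80 and 6.35 at 12, 16, 20 and 24 h, 343 on contact day 0 (2477 against 722.5 CPM, 282 to 419), 8.73 on day 3 and 1.99 on day 5. At serum 12 h, members of the miR-290 cluster of pluripotent cells were seen beside miR-291a-3p (115 reads): miR-292-3p had 63 reads, miR-293-3p 83 and miR-294-3p 85, against at most 13 in any other library. miR-295-3p and miR-293-5p of the same cluster went the other way, with 0 reads at 12 h and 38 and 12 at serum 0 h. At serum 0 h the blood miRNAs miR-142-3p and miR-142-5p had 62 and 45 reads, against 0 in every other library. The miR-142 and miR-290 cluster members not named by the rule for named miRNAs were chosen after their values were seen.

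A hypothesis was that arrest moves the same miRNAs in both experiments, since the log2 ratio of serum 0 h to the released mean and that of the later contact days to day 0 had a Spearman rho of 0.345 across 347 miRNAs, which are not independent replicates. Of 15 choices of 1 serum library as arrested and 1 contact library as not, the real one gave the highest rho, and the highest of the others was 0.331, with serum 16 h in place of 0 h. With the GC trend removed the real choice gave 0.293 and the highest other 0.235. The smallest share that 15 choices allow is 0.0667, so the hypothesis may hold but cannot be told apart from chance in this design.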
